A study of Mus musculus with 12 samples.

How the data were processed

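Gene expression was measured in peritoneal macrophages of female mice on 1-colour Affymetrix whole-transcript arrays. The 12 arrays fall into 4 groups of 3 by the sample titles: wild-type (C57Bl/6) and Nfkbiz-/- cells, each either left untreated or given 1 µg/ml lipopolysaccharide (LPS) for 4 h. Per the labels' protocols, cells were flushed from the peritoneal cavity, plated and cultured briefly, RNA was taken with an RNeasy kit, cDNA was made with the Ambion WT Expression kit and labelled with the GeneChip WT Terminal Labeling kit. No sort or gate is given in the labels. The labels do not say whether the replicates of a group came from separate mice, so the p-values measure only the spread between these samples, which may be technical.

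The deposited values are intensity values on a linear scale, 1 per probe set, summarised by the authors with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. Settings of that step are not given in the sources used here; RMA in general includes quantile normalization. The deposited intensity values ran from 6.96 to 22642, all above 0, and array medians lay between 110.4 and 118.7. The design had assumed values already on a log2 scale, so log2 of the deposited intensity was taken without a pseudocount. No pair of arrays held identical values, and correlations between arrays of 1 group were 0.982 to 0.996. Quantile normalization forces similar distributions on all arrays, so a change of most transcripts in 1 direction would not be seen, and intensities near the bottom of the range understate fold changes.

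Of 35556 probe sets, 21789 had 1 gene symbol in GEO's platform annotation, 1621 had several and 12146 had none. Through their Entrez identifiers, 21698 of those with 1 symbol were found in a RefSeq gene table of assembly GRCm38, 91 were not, and 0 symbols needed an update. No coordinates are given, because the build behind the array annotation is not given in the sources used here, and that table served only for names and for which genes neighbour each other. For 999 genes with several probe sets, the one with the highest mean over the 12 arrays was kept, which left 19938 genes. Where another probe set of a named gene gave a different call, this is said beside the gene.

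Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided) on log2 intensity, with 4 group means over the 12 arrays and 8 residual degrees of freedom per gene. The 5 contrasts were LPS against untreated in each genotype, knockout against wild type in each treatment, and the difference of both LPS responses (the interaction). P-values were adjusted by Benjamini-Hochberg over the 19938 genes, and a gene was called at an adjusted p under 0.05. The number of arrays limits the precision. On simulated data for the knockout against wild type comparison with LPS, run on 19938 genes, 93% of 2-fold and 98% of 4-fold changes were recovered, with 6 unchanged genes called. For the interaction, on the same number of genes, 85% of 2-fold and 99% of 4-fold changes were recovered, with 8 unchanged genes called. Changes were planted only in genes of brighter mean level, so recovery among dim genes was not tested. Of 50 random gene lists in the simulated data, 0 were called. Simulated genes varied independently, so this does not test lists whose members move together. The estimated correlation between interferon-stimulated genes on the real arrays was 0.88.

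Before the data were examined, 23 gene lists were fixed (pathways, and markers of other cells a peritoneal wash could hold), and 335 of their 373 entries were measured. Each list was tested per contrast with camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and the rotation test fry as alternatives. Members were also counted after adjustment over the list alone. The list of genes known to depend on IκBζ came from general knowledge of the field and not from these arrays.

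The rule for naming genes was also fixed beforehand. It takes Nfkbiz and Ccl2 throughout, the 6 called genes with the largest positive and the 6 with the largest negative difference in each contrast, and up to 4 members of each list with the largest absolute difference. It adds all measured members of the IκBζ-dependent, chemokine and cytokine lists for the LPS-treated genotype comparison and the interaction, and called genes among the 100 tested genes nearest to Nfkbiz. Predicted genes, small RNAs and olfactory or vomeronasal receptor genes were passed over. Pseudogenes by the RefSeq table were passed over as well, which the rule had not spelled out.

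Alternatives were other array scalings, a filter on dim genes, an intensity trend with robust estimation, array weights, a replicate block, all probe sets, fits on the 6 arrays compared, a stricter threshold, a minimum fold, and leaving out each array in turn. The titles number the replicates 1 to 3 in every group, and same-numbered arrays were compared by the correlation of their deviations from the group means across genes. These were 0.32, 0.57 and 0.46 between untreated and LPS-treated knockout arrays, so the numbers pair these samples by the data, though no label states a shared animal. For wild type they were -0.07, 0.14 and 0.36, and untreated replicate 2 with LPS replicate 1, of unlike number, gave 0.33. Whether numbers pair the wild-type arrays is therefore not settled. Between genotypes with LPS they were -0.06, -0.20 and -0.14, so those arrays share only a number. A block within genotype and a fit without both arrays whose interferon-stimulated level stands apart were added after seeing the data.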

Results

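Transcript levels were measured in peritoneal macrophages from wild-type mice and from mice lacking Nfkbiz, which encodes IκBζ, an LPS-inducible nuclear member of the IκB family. Cells were left untreated or given LPS, the bacterial cell-wall component sensed through TLR4, at 1 µg/ml for 4 h, with 3 arrays in each of the 4 groups. The series title names IκBζ as a regulator of Ccl2, which encodes the monocyte chemoattractant MCP-1. Values are mean intensity ± SD with n = 3, and differences are log2 with the standard error (SE) of the limma fit, whose Benjamini-Hochberg adjusted p is given throughout.

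The targeted gene was lower in every knockout array than in any wild-type array of the same treatment. In untreated cells, Nfkbiz read 462.6, 430.7 and 406.3 on the wild-type arrays and 266.9, 285.6 and 274.4 on the knockout arrays. With LPS it read 3371, 3786 and 3079 in wild type and 1568, 1335 and 1634 in knockout. The log2 difference was -1.17 with LPS (SE 0.10, limma adjusted p = 7.23e-05) and -0.65 without (SE 0.10, limma adjusted p = 0.0401). LPS raised the Nfkbiz signal in both genotypes, by 2.97 in wild type and 2.45 in knockout. Where the probe set lies relative to the deleted part is not given in the sources used here, so the remaining signal does not measure intact transcript. The untreated difference missed the threshold in 8 of the 12 fits that left out 1 array, at adjusted p up to 0.141 (-0.70, without wild-type untreated replicate 3).

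In wild-type cells the gene most raised by LPS was Il6. This cytokine gene of the acute phase rose from 104 to 11100 (log2 difference 6.80, SE 0.34, limma adjusted p = 1.32e-07), and Il23a (5.47), Csf3 (5.56), Lif (5.45) and the chemokine gene Cxcl10 (5.59) rose alongside it, as did Tpbpa (5.77), best known from the placenta. The genes that fell most were Rgs2, a regulator of G-protein signalling (-4.26), Tnfsf14 (-4.07), the amino-acid transporter gene Slc43a2 (-3.77), the proton pump gene Atp6v0d2 (-3.70) and Cd300lb (-3.67). Ccl2 rose from 568 ± 290 to 3610 ± 1470 (2.73, SE 0.53, limma adjusted p = 0.00219).

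By list, 19 of 23 cytokine genes rose in wild type with LPS and 0 fell (19 adjusted over the list alone, limma camera adjusted p = 3.02e-15, and 0.0368 with an estimated correlation). Of 22 chemokine genes, 12 rose, 1 fell and 9 were not called (14 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.79e-07, adjusted p = 0.0368 with an estimated correlation). Ccl4 (4.63) and Cxcl1 (4.50) rose with Cxcl10. Among 17 NF-κB members and feedback genes 15 rose (15 adjusted over the list alone), such as Tnfaip3 (2.80), which encodes the deubiquitinase A20, and Traf1 (2.03), with camera adjusted p = 8.39e-13 and an adjusted p = 0.0569 with an estimated correlation. Interferon-stimulated genes rose in 23 of 29 cases (27 adjusted over the list alone), among them Rsad2 (4.83) and Ifit1 (4.51), which encode antiviral proteins, with camera adjusted p = 1.35e-10 but an adjusted p = 0.49 with an estimated correlation. The mean log2 level of that list was 11.05, 11.89 and 9.54 on the LPS-treated wild-type arrays, so replicate 3 stood low, and the list's median response of 2.27 was 1.42 without replicate 2. Effector enzyme genes rose in 7 of 12 cases (7 adjusted over the list alone), Nos2 by 3.55 and Ptgs2, the inducible cyclooxygenase, by 2.14 (camera adjusted p = 4.58e-04, adjusted p = 0.055 with an estimated correlation). Immediate-early genes rose in 8 of 19 cases and fell in 1 (10 and 2 adjusted over the list alone, camera adjusted p = 0.00247, adjusted p = 0.244 with an estimated correlation). Antigen presentation genes rose in 6 of 18 cases and fell in 1 (camera adjusted p = 0.0497, adjusted p = 0.719 with an estimated correlation). That list call was lost in 7 of the 12 fits that left out 1 array, such as without LPS replicate 2 (0.20). The 7 genes known from earlier work to depend on IκBζ rose in 6 cases (camera adjusted p = 2.59e-08, adjusted p = 0.0251 with an estimated correlation).

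In total, 5594 of 19938 genes were called in wild type, 1900 higher and 3694 lower, and 1205 of them changed at least 2-fold. The share of higher calls depended on scaling: 34% as deposited, 44.5% after quantile normalization, and 72.8% after centring each array on its 75th percentile, which called 7416 higher and 2774 lower and shifted the median of all genes to 0.193.

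In knockout cells LPS raised Il6 most, as in wild type, but Csf3 and Lif were not among the 6 most raised genes. Il6 rose from 67.8 to 7070 (log2 difference 6.73, SE 0.34, limma adjusted p = 1.2e-07), and Cxcl10 (5.79), Tpbpa (5.55), Il23a (5.39) and Cxcl9 (5.34), an interferon-inducible T-cell attractant, were among the most raised. Csf3 rose by 2.26 (3.22 without LPS replicate 2 and 1.45 without LPS replicate 3) and Lif by 3.61. Abcd2, a peroxisomal transporter gene (-4.48), Vsir, which encodes the checkpoint protein VISTA (-4.25), Cd300lb (-3.88) and Nfam1 (-3.69) fell most. Ccl2 rose from 192 ± 106 to 596 ± 387 (1.55, SE 0.53, limma adjusted p = 0.0324). That call was lost without untreated replicate 1 (1.28) or 2 (1.40), and without LPS replicate 2 (1.57) or 3 (1.06), at adjusted p from 0.0598 to 0.125. These fits do not use the replicate numbers. By number, Ccl2 went from 120.8 to 265.9, from 142.1 to 500.5 and from 313.7 to 1022.

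In the knockout 20 of 23 cytokine genes rose (21 adjusted over the list alone, limma camera adjusted p = 1.17e-09), and of 22 chemokine genes 14 rose and 1 fell (15 and 1 adjusted over the list alone, camera adjusted p = 4.91e-06), both with an adjusted p = 0.151 with an estimated correlation. Interferon-stimulated genes rose in 27 of 29 cases (28 adjusted over the list alone, camera adjusted p = 6.86e-09, adjusted p = 0.518 with an estimated correlation), for example Ifit2 (5.40) and Gbp5 (4.94). Immediate-early genes rose in 14 of 19 cases and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 4.82e-05, adjusted p = 0.151 with an estimated correlation), with Maff (2.87) and Dusp5 (1.90) foremost. Of 17 sterol synthesis genes 12 fell and 0 rose (13 lower adjusted over the list alone, camera adjusted p = 3.5e-05, adjusted p = 0.501 with an estimated correlation), such as Dhcr7 (-1.90), Lss (-1.57), Mvd (-1.40) and Sqle (-1.40). NF-κB feedback genes rose in 14 of 17 cases and fell in 1 (camera adjusted p = 4.68e-08, adjusted p = 0.171 with an estimated correlation). Effector enzyme genes rose in 8 of 12 cases and fell in 1 (camera adjusted p = 0.00656, adjusted p = 0.151 with an estimated correlation). The 7 IκBζ-dependent genes rose in 5 cases and fell in 1 (camera adjusted p = 0.0498, adjusted p = 0.306 with an estimated correlation). Antigen presentation genes rose in 8 of 18 cases and fell in 1 (camera adjusted p = 0.0498, adjusted p = 0.703 with an estimated correlation). These list calls were lost in 5 and 7 of the 12 fits that left out 1 array, both of them without knockout untreated replicate 2 (1.04 and 0.28), knockout LPS replicate 3 (1.05 and 0.26) or wild-type LPS replicate 1 (adjusted p = 0.053 and 0.0555).

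The knockout response comprised 9105 called genes, 4365 higher and 4740 lower, 1830 of them at least 2-fold. Centring on the 75th percentile called 11026 higher and 3360 lower, a share of 76.6% against 47.9%, with a shift of all genes to 0.284. Both genotypes shared 4795 called genes, 4760 of them in the same direction. The count called in 1 genotype alone (799 in wild type and 4310 in knockout) does not show that the responses differ, which the interaction tests. Among 1454 genes that responded at least 2-fold averaged over both genotypes, the knockout response was smaller for 31.4%. The slope on the wild-type response was 1.039 (jackknife SD 0.084), with r = 0.934 across genes, which are not independent replicates. That r pools raised and lowered genes, and it was 0.597 among the 552 raised and 0.676 among the 902 lowered genes.

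The comparison of LPS-treated knockout with wild-type cells asks which stimulated levels depend on IκBζ. Csf2, which encodes the growth factor GM-CSF, was 44.7 in knockout and 1400 in wild type (log2 difference -4.97, SE 0.11, limma adjusted p = 3.15e-10). Lcn2, which encodes an iron-sequestering antimicrobial protein, was 79.5 against 1950 (-4.63, SE 0.25, limma adjusted p = 3.43e-06). Ccl2 was 596 ± 387 against 3610 ± 1470 (-2.74, SE 0.53, limma adjusted p = 0.00982), and every knockout array read below every wild-type array. Highest above wild type stood Cxcl9, at 4410 against 349 (4.13, SE 0.54, limma adjusted p = 0.00113). Among called genes that the naming rule takes, the interferon-inducible Iigp1 (3.38), Tnfsf10 (3.32), Ifit3b (3.24) and Gbp4 (3.16) came next. Of these, Iigp1, Tnfsf10 and Gbp4 lost their calls without wild-type replicate 3 (2.27, 2.61 and 2.46), wild-type replicate 1 (3.35, 3.15 and 2.98) or knockout replicate 3 (3.28, 2.95 and 2.78), and Iigp1 in 9 of the 12 fits that left out 1 array. Vcam1, which encodes a leukocyte adhesion molecule, followed at 2220 against 240 (3.10, SE 0.35, limma adjusted p = 5.17e-04).

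**Figure D1:**
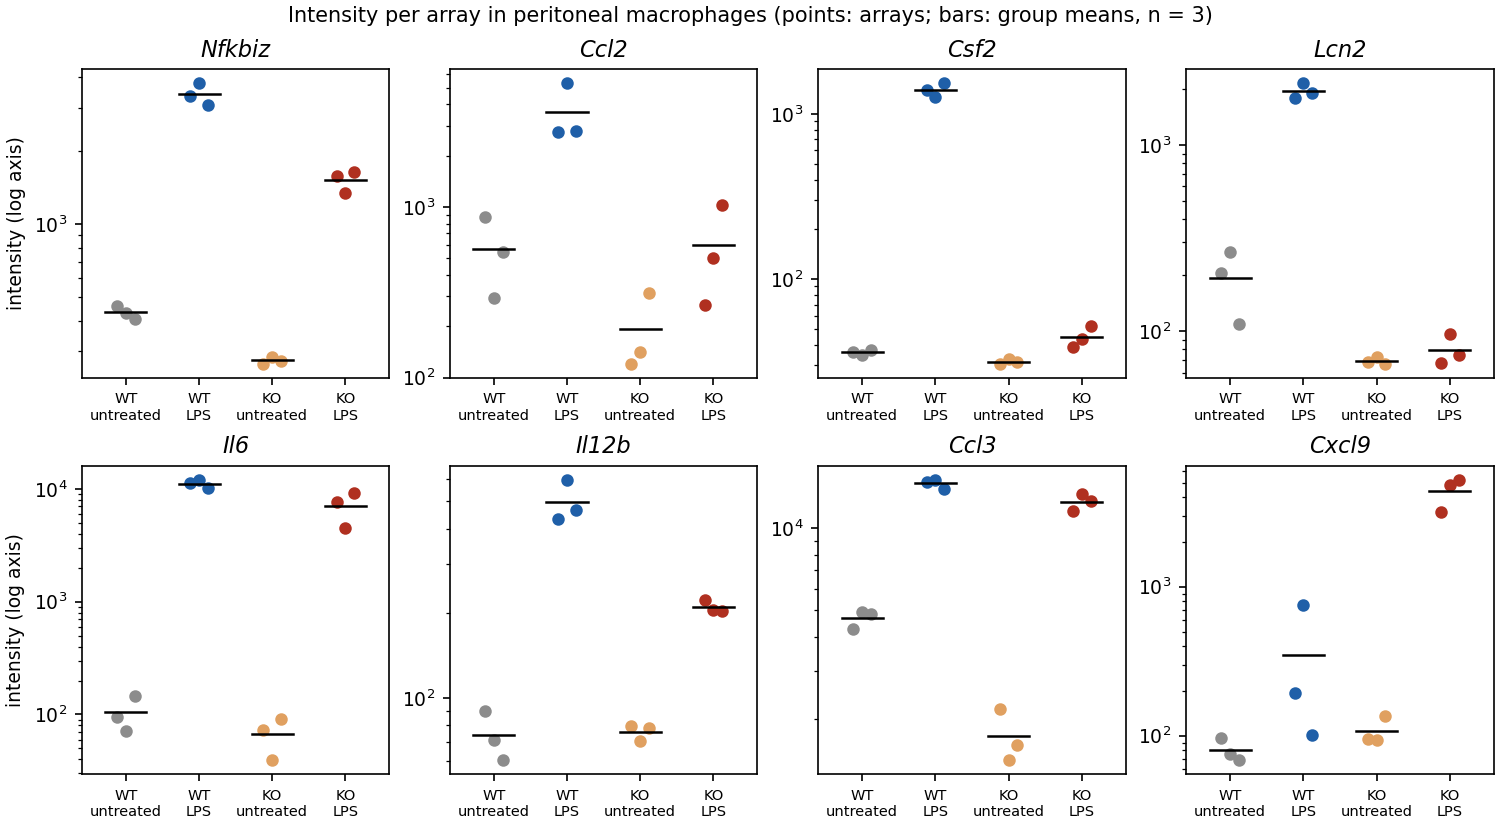
Intensity on each array, on a log axis, for 8 genes in the 4 groups of 3 arrays, with bars at the group means. In knockout cells Csf2 read 31.5 untreated and 44.7 with LPS, and Lcn2 69.3 and 79.5, while Il6 reached 7070 there against 11100 in wild type.

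Of the 7 genes known to depend on IκBζ, 6 were lower in LPS-treated knockout cells (6 adjusted over the list alone, median -1.92, limma camera adjusted p = 8.69e-13, adjusted p = 0.00471 with an estimated correlation). Besides Csf2 and Lcn2 these were Csf3 (-3.67), Edn1 (-1.92), Il12b (-1.23), which encodes the shared subunit of IL-12 and IL-23, and Cebpd (-0.94). Il6 was not called (-0.71, SE 0.34, adjusted p = 0.248), although every knockout array read below every wild-type array. It read 7572, 4514 and 9119 in knockout and 11200, 12090 and 10080 in wild type, so knockout replicate 2 stood lowest.

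Among 22 chemokine genes 5 were lower, 2 higher and 15 not called (6 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.0674, fry adjusted p = 0.0211). Ccl7, a close relative of Ccl2, was lower by 3.40 (log2 difference -3.40), Ccl17 by 3.29 (-3.29) and Cxcl5 by 2.68 (-2.68). Ccl17 already stood lower without LPS (-3.44), which did not pass (adjusted p = 0.0656), and its interaction was 0.15 (adjusted p = 0.965). Cxcl3 differed by -0.85, a call lost without wild-type replicate 1 (-0.83) or 3 (-0.89) or knockout replicate 2 (-0.81) or 3 (-0.79). The interferon-inducible Cxcl9 and Cxcl11 (2.38) were higher. Of 23 cytokine genes 6 were lower and 2 higher (7 lower and 6 higher adjusted over the list alone, camera adjusted p = 0.21, fry adjusted p = 0.0195), with Lif (-2.07) and Il19 (-1.25) lower and Il15 (2.82) and Il27 (1.54) higher. The Il15 call was lost without wild-type replicate 1 (2.74, adjusted p = 0.0626), and the Il27 call without both arrays of deviating interferon-stimulated level (1.16, adjusted p = 0.0505). Il23a (0.00), Il1b (0.02) and Tnf (0.38) were not called. Knockout replicate 2 stood low at Lif (1332, 435.9 and 1655 on the LPS-treated knockout arrays) and at Inhba (12460, 4405 and 12520). It stood high at Tnf (10630, 18090 and 11890).

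Sterol synthesis genes were lower in 10 of 17 cases and higher in 0 (11 lower adjusted over the list alone, median -0.48, limma camera adjusted p = 7.83e-09, adjusted p = 0.485 with an estimated correlation), with Sqle (-1.09), Lss (-0.99) and Msmo1 (-0.86) as examples. Glycolysis and hypoxia genes were lower in 6 of 15 cases (8 adjusted over the list alone, median -0.39, camera adjusted p = 2.52e-05, adjusted p = 0.485 with an estimated correlation), led by Pfkfb3 (-2.87), which makes an activator of phosphofructokinase, and without knockout replicate 2 the list median was -0.20. Interferon-stimulated genes had a median of 1.08 (camera adjusted p = 8.58e-10, adjusted p = 0.485 with an estimated correlation), but 2 of 29 were called higher (3 adjusted over the list alone). Their mean level was 12.03, 12.11 and 12.27 on the knockout arrays, and without wild-type replicate 3 the median difference was 0.46. Antigen presentation genes were higher in 4 of 18 cases and lower in 1 (7 and 2 adjusted over the list alone, median 0.38, camera adjusted p = 0.00283, adjusted p = 0.485 with an estimated correlation). Toll-like receptor signalling genes moved both ways, 4 higher and 4 lower of 21 (5 and 4 adjusted over the list alone, camera adjusted p = 0.847). Irf5 (0.91) and Tlr7 (1.13) were higher, and Irak3, an inhibitor of the pathway, was lower (-0.99, SE 0.10, limma adjusted p = 1.72e-04).

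**Figure D2:**
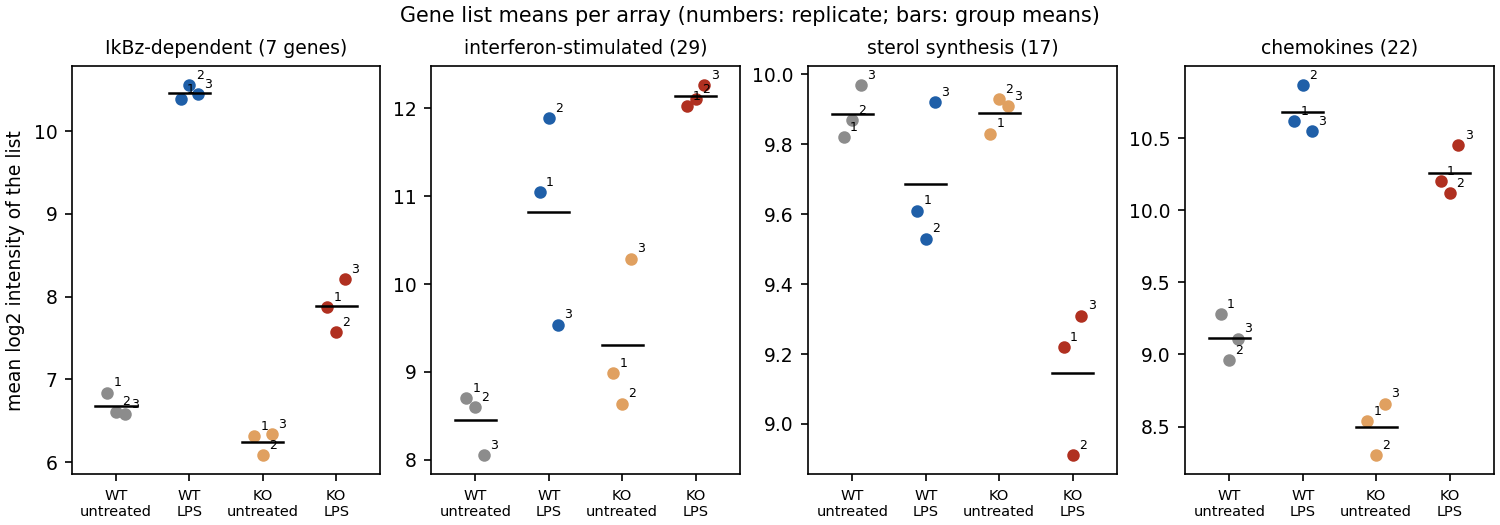
Mean log2 intensity of 4 fixed gene lists on each array, with replicate numbers and group means. On LPS-treated arrays the IκBζ-dependent list averaged 10.47 in wild type and 7.88 in knockout, while the interferon-stimulated list ranged from 9.54 to 11.89 among wild-type arrays alone.

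With LPS, 1623 genes were called between genotypes, 653 higher and 970 lower in knockout, and 275 differed at least 2-fold. Without wild-type replicate 3 the count was 712, without wild-type replicate 1 it was 754, without knockout replicate 3 it was 1076, and without both arrays of deviating interferon-stimulated level it was 655. The share of higher calls was 40.2% as deposited and 52.6% after centring on the 75th percentile. Among the 100 tested genes nearest to Nfkbiz, 7 were called where 8.14 would be expected (Fisher's exact test, one-sided p = 0.714), among them the noncoding Dubr (-1.26), Riox2 (-1.12) and Tbc1d23 (0.97). Many of the 100 are olfactory receptor genes, none of them called, so that expectation may be too high and an excess is not excluded. Tbc1d23 stood higher untreated too, without passing (0.91, limma adjusted p = 0.0872).

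Untreated knockout and wild-type cells differed at few genes, and several of those encode chemokines. Ppbp, which encodes a neutrophil-attracting CXC chemokine, was 327 ± 60.7 in knockout and 1880 ± 599 in wild type (log2 difference -2.49, SE 0.20, limma adjusted p = 9.39e-04). Cxcl3 (-1.84), Cxcl5 (-1.78) and Ccl3 (-1.45) were lower too, as was Cxcl2 (-0.68, adjusted p = 0.00121), which the naming rule does not take here and which was named after its values were seen. The lipid-synthesis gene Me1 was higher, at 764 against 234 (1.70, SE 0.14, limma adjusted p = 9.39e-04), and so was the acute-phase gene Orm1 (1.31). The calls of Cxcl5 (-1.81) and Orm1 (1.22) were lost without wild-type replicate 3. Mrc1, the macrophage mannose receptor gene, was called lower (-1.67), and Aldh1a2, a retinoic acid-making enzyme gene, likewise (-2.26), but these calls were lost in 5 and 9 of the 12 fits that left out 1 array, for example without wild-type replicate 3 (-1.58 and -2.13). Ccl2 (-1.56, SE 0.53, limma adjusted p = 0.442) was not called, although its means were 192 and 568.

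Of 22 chemokine genes 4 were lower and 0 higher in untreated knockout cells (9 lower and 1 higher adjusted over the list alone, median -0.42, limma camera adjusted p = 5.71e-06, adjusted p = 0.153 with an estimated correlation), and the median was -0.20 without knockout replicate 3. Interferon-stimulated genes had a median of 0.70 with 0 of 29 called (0 adjusted over the list alone, camera adjusted p = 5.9e-11, adjusted p = 0.447 with an estimated correlation). Their mean level was 8.99, 8.64 and 10.29 on the knockout arrays, and without knockout replicate 3 the median was 0.32. Mast cell markers had a median of 0.40 with 0 of 12 called (0 adjusted over the list alone, camera adjusted p = 4.37e-05, adjusted p = 0.409 with an estimated correlation), or 0.20 without knockout replicate 3. Small macrophage, monocyte and dendritic cell markers had a median of -0.45 with 0 of 11 called (0 adjusted over the list alone, camera adjusted p = 0.0254, adjusted p = 0.283 with an estimated correlation), a list call lost without knockout replicate 1 (-0.23) or 2 (-0.29) or wild-type replicate 1 (-0.30). Immediate-early genes had a median of -0.18 with 0 of 19 called (1 lower adjusted over the list alone, camera adjusted p = 0.00497, adjusted p = 0.324 with an estimated correlation). The IκBζ-dependent list had a median of -0.34 with 0 of 7 called (1 lower adjusted over the list alone, camera adjusted p = 0.0207, adjusted p = 0.283 with an estimated correlation). That list call was lost without wild-type replicate 1 (-0.19) or knockout replicate 2 (-0.23). Antigen presentation genes had a median of 0.14 (camera adjusted p = 0.00497, adjusted p = 0.509 with an estimated correlation). Glycolysis genes had one of -0.16 (camera adjusted p = 0.047, adjusted p = 0.629 with an estimated correlation). These calls were lost without knockout replicate 3 (0.11) and, for glycolysis, in 8 of the 12 fits that left out 1 array, such as without knockout replicate 2 (-0.07).

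In all, 15 genes were called in untreated cells, 7 higher and 8 lower in knockout, and 12 of them were called with LPS as well, all 12 in the same direction. The count without 1 array ranged from 6 (without wild-type untreated replicate 3) to 23 (without knockout LPS replicate 2), and was 8 without LPS replicate 1 of either genotype and 9 without knockout untreated replicate 1. The share of higher calls was 46.7% as deposited and 63.2% after centring on the array median.

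The interaction asks which genes responded to LPS differently in knockout and wild-type cells. Csf2 rose by 5.27 in wild type and by 0.49 in knockout, where limma still called it (adjusted p = 0.0028, interaction -4.78, SE 0.15, limma adjusted p = 2.62e-08), and Lcn2 had 3.42 against 0.18 (-3.24, SE 0.36, limma adjusted p = 0.00262). Tpbg, which encodes a trophoblast glycoprotein, had 3.05 against 0.44 (-2.61, SE 0.19, limma adjusted p = 1.09e-04). Lrrc25 had 0.34 in wild type and -2.78 in knockout (-3.12, SE 0.14, limma adjusted p = 9.61e-07), and the iron transporter gene Slc11a2 had 0.83 and -1.61 (-2.44). In the other direction stood Clic5 (2.29), Bmp2 (2.05), which encodes a bone morphogenetic protein, Klf8 (1.95) and Intu (1.95). For Ccl2 the interaction was -1.18 (SE 0.75), which did not pass (limma adjusted p = 0.552). It was -0.70 without knockout LPS replicate 1, -0.76 without knockout untreated replicate 3 and -0.77 without wild-type untreated replicate 2, and -1.68 without knockout LPS replicate 3. The Il6 response differed by -0.07 (SE 0.48, adjusted p = 0.972). Untreated Il6 read 94.74, 71.69 and 146.5 in wild type and 72.63, 39.55 and 91.23 in knockout, mostly below the array medians of 110.4 to 118.7. Its rise is thus measured from low intensities, and the similar log2 responses do not show that Il6 is independent of IκBζ.

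**Figure D3:**
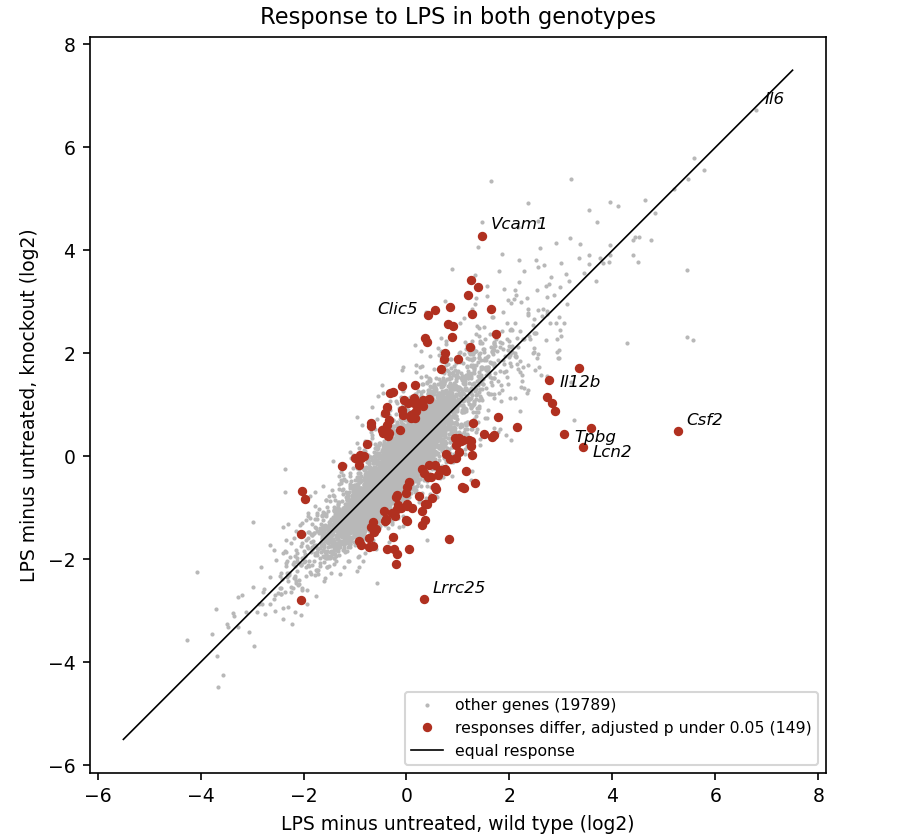
Log2 difference between LPS-treated and untreated cells for 19938 genes, wild type on the x axis and knockout on the y axis, with the 149 genes whose responses differ in red and a line of equal response. Csf2 lies at 5.27 and 0.49, and Il6 near the line at 6.80 and 6.73, measured from untreated levels mostly below the array medians.

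Of the 7 IκBζ-dependent genes 4 had a smaller response in knockout (6 adjusted over the list alone, median -1.58, limma camera adjusted p = 9.42e-13, adjusted p = 0.00476 with an estimated correlation), namely Csf2, Lcn2, Edn1 and Il12b. The Edn1 call (-1.58) was lost in 10 of the 12 fits that left out 1 array, at adjusted p up to 0.127 (-1.48, without wild-type untreated replicate 3), and the Il12b call (-1.29) without wild-type untreated replicate 2 (-1.27) or knockout untreated replicate 1 (-1.26). Among 22 chemokine genes Ccl3 (1.23) and Cxcl2 (0.63) had larger responses from their lower untreated level (5 higher and 2 lower values adjusted over the list alone, camera adjusted p = 0.463). Both gene calls were lost without both arrays of deviating interferon-stimulated level. With LPS, Ccl3 read 14690, 15040 and 13910 in wild type and 11510, 13350 and 12570 in knockout, and Cxcl2 11030, 11130 and 10710 against 10640, 10620 and 10430. Whether high intensities limit these levels was not tested, so the larger responses may reflect the lower start alone. Sterol synthesis genes had a median of -0.48 with 0 of 17 called (9 with a lower value adjusted over the list alone, camera adjusted p = 2.81e-10, adjusted p = 0.353 with an estimated correlation), and immediate-early genes a median of 0.31 with 0 of 19 called (2 adjusted over the list alone, camera adjusted p = 3.39e-04, adjusted p = 0.353 with an estimated correlation). Glycolysis and hypoxia genes had a median of -0.19 with 0 of 15 called (2 with a lower value adjusted over the list alone, camera adjusted p = 0.00523, adjusted p = 0.927 with an estimated correlation). That list call was lost without knockout LPS replicate 2 (-0.07) or untreated replicate 3 (-0.11).

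In total 149 genes were called in the interaction, 89 with a lower and 60 with a higher value in knockout, 76 of them at least 2-fold, and 145 of them were also called between LPS-treated knockout and wild-type cells, a comparison that uses the same LPS-treated arrays. A replicate block within genotype, chosen after seeing the data, called 296. Leaving out 1 array gave 60 (wild-type LPS replicate 1), 365 (wild-type LPS replicate 2), 86 (wild-type LPS replicate 3), 63, 68 and 67 (wild-type untreated replicates 1, 2 and 3), 55 (knockout untreated replicate 1) and 91 (knockout untreated replicate 3), and leaving out both arrays of deviating interferon-stimulated level gave 45. The share of higher values was 40.3% as deposited and 55.6% after centring on the 75th percentile.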

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

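The tests of single arrays, of small-macrophage markers and of the link between sterol and interferon-stimulated levels, the breakdown of other splits by pairs and by LPS-treated arrays, the interaction assignments that keep pairs together, the activation values of bright genes and without 1 array, and the exact permutation of list means were chosen only after the result was seen, and the requirement on marker brightness was added after the marker result was known.

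A test of the difference between both LPS responses (limma interaction) singled out 20 of the named genes. The knockout response minus the wild-type response was below 0 on the log2 scale for Csf2 (-4.78), Lcn2 (-3.24), Lrrc25 (-3.12), Gja1 (-3.03), Tpbg (-2.61), Slc11a2 (-2.44), Edn1 (-1.58), Il12b (-1.29), Tyms (-1.06), Riox2 (-1.02), Csf3r (-0.85) and Irak3 (-0.71). It was above 0 for Cxcl2 (0.63), Ccl3 (1.23), Klf8 (1.95), Intu (1.95), Bmp2 (2.05), Rnf225 (2.16), Clic5 (2.29) and Vcam1 (2.82). Csf3r fell in both genotypes (-0.88 in wild type and -1.72 in knockout), so its value means a larger fall. The calls of Gja1, Tyms, Csf3r, Vcam1 and Rnf225, like that of Edn1, were lost in most fits that left out 1 array.

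Other divisions of the arrays were tried for each count. The 6 arrays of a pairwise comparison allow 10 splits, too few for a share under 0.05. Every other split mixes the real groups, so a real difference swells its spread and keeps its count low. Such low counts do not measure false calls. The real split called 5594 genes for LPS in wild type (highest other 0), 9105 for LPS in knockout (highest other 1), 1623 between genotypes with LPS (highest other 1) and 15 untreated (highest other 0), so that 1 of the 10 splits reached the real count in each case. For the knockout response, where numbers pair the arrays, the 3 other splits that part all 3 pairs called 0 genes at most, and the 6 that part fewer pairs called 1 at most. For the interaction, 6 of 100 assignments of genotype within treatment called at least 149 genes, so chance is not excluded by this count. These assignments break the pairs of same-numbered knockout arrays, and the 9 others of 10 that keep same-numbered arrays together, too few for a share under 0.05, called 0 genes at most. The highest other called 1076, and all 5 others as large kept the real genotypes of the LPS-treated arrays, so they carry the genotype difference with LPS itself, a structure of the samples. The 91 assignments that moved LPS-treated arrays between genotypes called 0 genes at most, but like the 9 above they mix the real groups, with the same limit.

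Interferon-stimulated genes had higher medians in knockout cells, 1.08 with LPS and 0.70 untreated. The lowest median under 3 other scalings was 1.06 with LPS. Array medians as deposited already lay between 110.4 and 118.7, so rescaling could move that value only little. These scalings therefore cannot decide whether the normalization before deposit has a part. A single array remains open as the source in either state. Without wild-type LPS replicate 3 the median was 0.46, below the SD of 0.59 between the remaining pair of wild-type arrays, and without knockout untreated replicate 3 it was 0.32, below the SD of 0.35 between wild-type untreated arrays. A genotype effect on interferon signalling may exist but is not separated from these arrays, and an exact permutation test of the list mean with LPS gave a difference of 1.31 at two-sided p = 0.1, the smallest that 3 against 3 arrays can give, and untreated 0.86 at p = 0.2.

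The 5 chemokine genes lower in untreated knockout cells (Ppbp, Cxcl3, Cxcl5, Ccl3 and Cxcl2, median -1.78) raise the question of what else differs between the cells. That these genes lie on a chromosomal segment carried with the targeted allele is argued against, as 0 of the 5 are among the 100 tested genes nearest to Nfkbiz. This count is set by the gene map and not by these arrays. It cannot speak to effects of such a segment on genes elsewhere, or to other differences in genetic background. The backcross history of the knockout is not given in the sources used here. Uniformly less activation of knockout cells during preparation is argued against as the whole cause, but only weakly. The 132 other genes induced at least 4-fold by LPS had a median of 0.06, and 0.00 without knockout untreated replicate 3. The 43 of them bright enough to show as large a fall as the chemokines' had a median of -0.08, and -0.13 without that array. Bootstrap 95% intervals were -0.01 to 0.12 and -0.27 to 0.08. They resample genes measured on the same arrays and do not measure the spread between arrays. Of interferon-stimulated genes, only those on the fixed list were set aside. Others remain among the bright genes and raise their median, such as Slfn4 (1.11), Irgm1 (0.74) and Trim30d (0.52), as that list ran higher in untreated knockout cells. Medians without such genes were not computed. Weaker or selective activation stays open. Of the 43 bright genes 22 were lower, a count that mixes in those interferon-inducible genes and so does not show the absence of a shift. The largest falls were Nr4a3 (-1.67) and Upp1 (-1.31), and the largest rises AW112010 (1.22) and Slfn4 (1.11), none of them called. The immediate-early list (median -0.18, camera adjusted p = 0.00497, 0.324 with an estimated correlation) and the IκBζ-dependent list (-0.34, adjusted p = 0.0207, 0.283 with an estimated correlation) ran towards lower values. Fewer small macrophages, monocytes and dendritic cells cannot be told apart from a genotype effect. Of the expressed markers 6 of 6 were lower, with a median of -0.70 (95% bootstrap interval over genes -1.24 to -0.31, with the same limit). But only 1 of them was bright enough to show a fall as large as the chemokines'. Before that requirement was added, the interval alone had counted against this explanation. An effect of IκBζ on resting chemokine expression stays a hypothesis beside it.

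Sterol synthesis genes were lower in LPS-treated knockout cells, with a median of -0.48. Wild-type LPS replicate 3 as the whole source is argued against, but only weakly. Without it the median was -0.38, against an SD of 0.06 between the remaining wild-type arrays, which rests on 2 values. The list mean was 9.61 and 9.53 on those arrays and 9.22, 8.91 and 9.31 on the knockout arrays, whose SD was 0.21. Without wild-type LPS replicate 3, 4 rather than 10 genes were called. A link to the interferon-stimulated level of each array stays open: over 12 arrays, deviations of both list means from their group means gave Pearson r = -0.54 (exact permutation within groups, one-sided p = 0.101) and Spearman rho = -0.59 (exact permutation, one-sided p = 0.0563), 1 relation tested. Without the 2 arrays farthest out, wild-type LPS replicates 2 and 3, r was -0.08, so the relation rests on those arrays. Lower sterol synthesis in LPS-treated cells without IκBζ may be followed up as a hypothesis, and camera with an estimated correlation did not call it (adjusted p = 0.485).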

How the results depend on the processing

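All alternatives were chosen beforehand except leaving out both arrays of deviating interferon-stimulated level and the block within genotype, chosen after seeing the data. The cause of each change was not tested, except that a stricter threshold or a minimum fold calls fewer genes by construction. Low intensities limit what dim genes can show.

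LPS in wild type called 10190 genes after centring on the 75th percentile, 10113 with array weights (the weights ran from 0.40 to 6.25), 3673 at an adjusted p under 0.01 and 1205 at 2-fold or more. Knockout replicate 2 had the lowest weights, 0.49 untreated and 0.40 with LPS, and wild-type LPS replicate 1 had the highest. LPS in knockout called 14386 after centring on the 75th percentile, 5936 at an adjusted p under 0.01 and 1830 at 2-fold or more. Knockout against wild type with LPS called 3296 with array weights, 492 on the 6 arrays compared, 552 at an adjusted p under 0.01, 275 at 2-fold or more, and 655 without both arrays; leaving out 1 array gave 712 to 2158. Untreated, the counts were 24 after quantile normalization, 25 with the 75th percentile, 46 with weights, 30 with the replicate block, 2 on the 6 arrays, 7 at 0.01 and 9 at 2-fold or more, and 6 to 23 with 1 array left out. The interaction called 667 with weights, 86 with all probe sets, 39 at 0.01, 76 at 2-fold or more, 45 without both arrays, 296 with the replicate block within genotype, and 55 to 365 with 1 array left out.

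Untreated Nfkbiz lost its call after median centring (-0.61, limma adjusted p = 0.0615), with the replicate block (-0.65, adjusted p = 0.0614), with all probe sets (-0.65, adjusted p = 0.0838) and without both arrays (-0.65, adjusted p = 0.1); with 1 array left out it ranged from -0.70 to -0.60. Ccl2 with LPS kept its call in the 12 fits that left out 1 array, from -3.23 to -2.26, while its rise in knockout lost its call with the intensity trend and robust fit (1.55, adjusted p = 0.0619). That fit also ended the calls of Iigp1 (0.0912) and Gbp4 (0.0533) with LPS, Aldh1a2 untreated (0.0891), and Vcam1 (0.0614), Rnf225 (0.0627), Gja1 (0.101) and Edn1 (0.0555) in the interaction. The replicate block ended those of Iigp1 with LPS (0.0597) and of Edn1 (0.0833) and Csf3r (0.0672) in the interaction. Without both arrays the interaction calls of Ccl3 (0.0918) and Cxcl2 (0.0648) were lost. The block within genotype, which covers the LPS responses and the interaction only, changed no list call. Among named genes there, 2 calls were lost and 27 gained with it. Over all named genes and comparisons, calls lost and gained were 26 and 0 with all probe sets, 11 and 1 with the trend, 10 and 15 with the replicate block, 11 and 6 after quantile normalization, 6 and 0 after median centring, 4 and 28 with the 75th percentile, 4 and 60 with weights, 0 and 9 without dim genes, and 36 and 6 without both arrays.

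Reversals were 1 list and 1 gene: B-cell markers in untreated cells without knockout replicate 2 (0.10, adjusted p = 0.0179; range with 1 array left out -0.17, without wild-type untreated replicate 3, to 0.10) and Il23a with LPS without knockout replicate 2 (0.45, adjusted p = 0.0449; range -0.27, without knockout LPS replicate 3, to 0.45), neither called in the full fit. Calls of the untreated genes Acsf2 and Lrrk2 were lost with their other probe set (adjusted p = 0.0699 and 0.514).

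By fry, calls were gained between LPS-treated genotypes for chemokines (adjusted p = 0.0211) and cytokines (0.0195), and with LPS in wild type for antimicrobial genes (0.00557), besides the cell markers named elsewhere. By fry, list calls were lost for interferon-stimulated genes with LPS (adjusted p = 0.224) and untreated (0.438), antigen presentation with LPS (0.224), and in untreated cells also for mast cell markers and glycolysis (0.438 each), antigen presentation (0.503), and small macrophage markers, large macrophage markers, immediate-early and IκBζ-dependent genes (0.0936 each). In the interaction it was lost for sterol synthesis and immediate-early genes (0.103 each) and glycolysis (0.519), the last also without dim genes (0.0514). Centring on the 75th percentile ended the list calls of immediate-early genes (0.0691) and antigen presentation (0.352) in wild type, and of antigen presentation (0.351), IκBζ-dependent genes (0.249) and effector enzymes (0.0981) in knockout. The knockout call of IκBζ-dependent genes was also lost after quantile normalization (0.0514) and with the replicate block (0.0508), as were those of antigen presentation with the block (0.0683 in wild type and 0.0535 in knockout).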

Other observations

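With LPS, camera called none of the lists of lymphocyte, granulocyte, erythroid and mesothelial markers. B-cell markers fell with LPS in 4 of 14 cases in wild type and 5 of 14 in knockout, Cd79b by a log2 value of -0.98 and -1.27, while the list was not called (limma camera adjusted p = 0.411 and 0.243). Neutrophil markers showed 1 higher and 2 lower of 13 in wild type (adjusted p = 0.668), with Csf3r at -0.88 and Mmp8 at -0.80, and 3 higher and 2 lower in knockout (adjusted p = 0.949). Of the eosinophil list 2 of 6 genes fell in wild type (adjusted p = 0.515), including Alox15 (-0.76), which large peritoneal macrophages also express and their list holds too, and in knockout 3 rose and 2 fell (adjusted p = 0.972). Of mesothelial markers 1 of 11 rose in wild type (0 adjusted over the list alone, camera adjusted p = 0.141) and 3 in knockout (adjusted p = 0.115). Of T and NK cell markers 0 of 14 rose in wild type (adjusted p = 0.411) and 3 in knockout (adjusted p = 0.283). Of erythroid markers 0 of 3 rose in wild type (adjusted p = 0.411) and 1 in knockout (0 adjusted over the list alone, adjusted p = 0.392). The rotation test fry, which does not compare with other genes, called mesothelial (limma adjusted p = 0.0177 and 0.00281) and erythroid markers (0.00557 and 7.95e-04) in both genotypes and T and NK cell markers in knockout (0.0159). The Y-linked genes, measured in female mice, had 0 of 3 called in either (camera adjusted p = 0.668 and 0.762).

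Markers of large peritoneal macrophages were not called as a list between LPS-treated genotypes, 2 higher and 1 lower of 14 (limma camera adjusted p = 0.317), nor were those of small macrophages, monocytes and dendritic cells, 0 of 11 (adjusted p = 0.583). Yet the list mean of the former was 11.29, 11.34 and 11.22 on the LPS-treated knockout arrays against 11.04, 11.06 and 11.12 in wild type, and that of the latter 6.62, 6.52 and 6.67 against 6.85, 6.91 and 7.02. Whether cell composition has a part in the lower Ccl2, Ccl7 and Ccl17 levels with LPS was not tested. Timd4 read 719.3, 2608 and 1156 in knockout and 325.7, 384.3 and 372.2 in wild type without passing (log2 difference 1.85, adjusted p = 0.0721). In untreated cells 0 of 14 were called (median 0.14, camera adjusted p = 0.0112, adjusted p = 0.153 with an estimated correlation), and the list call was lost without wild-type untreated replicate 1 (0.21, adjusted p = 0.0586). Mast cell genes were not called in LPS-treated knockout cells, 0 of 12 (median 0.39, adjusted p = 0.0674), and the median was 0.12 without knockout replicate 3 and 0.24 without wild-type replicate 1. The list mean was 7.38, 6.58 and 7.85 on the knockout arrays and lay between 6.70 and 7.08 in wild type. Mcpt4 varied likewise, at 265.4, 86.2 and 648.4 in knockout. The exact permutation test of that list mean gave a difference of 0.45 untreated (two-sided p = 0.1, the smallest possible) and 0.34 with LPS (p = 0.5).

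Of 20 cell cycle genes, LPS raised 2 and lowered 5 in wild type (limma camera adjusted p = 0.633). Mki67 (2.47) rose while the replication licensing genes Mcm7 (-0.65) and Mcm4 (-0.64) fell, the last a call lost without wild-type LPS replicate 2 (-0.51, adjusted p = 0.0534). Antimicrobial and acute-phase genes, led by Lcn2 and the complement gene Cfb (1.07), rose in 4 of 14 cases and fell in 1 (adjusted p = 0.141, fry adjusted p = 0.00557).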
